A study of Rattus norvegicus with 16 samples.

How the data were processed

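Genomic DNA of hippocampus and hypothalamus of male Sprague Dawley rats was digested with MspI, from about 1000 ng per library, and fragments of 150 to 300 bp were bisulfite-treated and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Per the labels, rats in the study received fructose or docosahexaenoic acid (DHA) or both for 6 weeks; libraries of rats given DHA were not analysed here. The 16 libraries analysed were 4 control and 4 fructose libraries of each tissue, grouped by their titles, with replicate numbers from the same titles. Per the labels, the treatment tag of the controls reads control in hippocampus and none in hypothalamus; both were taken as untreated, which the tissue comparison rests on. Reads were mapped with Bowtie to the rn5 assembly, per the submitters' processing notes; the version of Bowtie, the methylation caller and the handling of duplicate reads are not given in the sources used here.

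The authors deposited 1 table per library with no header, 1 row per cytosine of 1 strand. Its columns gave, as read from the values, the chromosome, the base, the position counted from 1, the sequence context, the methylation level, and the counts of methylated and of all reads. The deposited level is a fraction between 0 and 1 that equals the deposited methylated count over the deposited total count in every row, with no correction for unconverted cytosines. The deposited counts list only cytosines with at least 10 reads, and no total exceeded 8031 reads. Each library held between 8,699,068 and 11,540,233 cytosines. The tables cover 20 autosomes, the X chromosome and mitochondrial DNA. All coordinates are those of rn5 as deposited, counted from 1.

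No genome or annotation of rn5 was used here. CpGs were therefore not tied to genes, promoters or CpG islands, and lists of genes fixed in advance, among them markers of brain cell types, were not tested. As the written design foresaw for this case, 1 kb tiles by coordinate took the place of gene regions.

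From the counts, both strands of each CpG were summed. A CpG entered a comparison with at least 10 reads in every library of the fit and a pooled level of 5% to 95%. A tile needed at least 3 CpGs with 10 reads in every library, whose reads were summed, and a pooled level of 1% to 99%. Group levels are unweighted means over libraries of the level per library, with SD over the 4 libraries. Each CpG or tile was tested with a quasi-binomial logistic model on methylated and unmethylated counts across replicates. The Pearson dispersion was squeezed across sites by the empirical Bayes method of limma and held at 1 or more, and the group term was tested with a two-sided F-test and a Benjamini-Hochberg adjusted p under 0.05. In the fit the level of a group is that of its summed reads, so deeper libraries weigh more. The spread between replicates enters through the dispersion, which is in part shared across sites. Depth can therefore still weigh on a p-value where it differs widely between libraries. The difference between the fructose effects of the 2 tissues was the tissue by treatment term in a fit of all 16 libraries. Median depth of a tested CpG per library was 54 reads in the hippocampus comparison, 47 in the hypothalamus comparison and 54 in the tissue comparison. Reads carry no molecular identifiers here, so they need not be independent molecules.

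Global measures were computed per library: the mean level over CpGs with 10 reads in all 16 libraries, and read-weighted methylation of cytosines outside CpG on autosomes by context (CHG, CHH) and by the next base (CA, CT, CC). Group means were compared by two-sided exact permutation over all 70 arrangements of 4 against 4, whose smallest p is 0.0286, adjusted over the 6 measures of a comparison. Libraries were also split at 1% CC methylation as a sign of conversion batch, a split chosen after the values were seen.

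The CpGs named are, per comparison, the 5 with the largest rise and the 5 with the largest fall among called CpGs whose groups do not overlap, at most 1 per 10 kb. The tiles named are the 8 with the smallest p in each direction among called tiles, tiles of 5 or more CpGs first; if fewer passed, all that passed and the 3 smallest p of the rest. For the tissue by treatment term these were the 5 smallest p. Groups, tests, this rule and most of the alternatives below were fixed before the data were examined.

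The test was run on simulated counts with the depths and dispersions of the real libraries and 200 changed sites. For hippocampus CpGs, with 592,234 simulated, it recovered 2% of changes of 10 points, 24% of 20, 72% of 30 and 84% of 40 points, and 14 of 105 calls were unchanged CpGs. For hypothalamus CpGs the shares were 2%, 12%, 66% and 96%, with 3 of 91 calls unchanged, and for the tissue comparison 2%, 24%, 60% and 84%, with 14 of 99 unchanged. In hippocampus tiles 48% of changes of 20 points and 82% of 30 points were recovered, in hypothalamus tiles 62% and 80%, and in tissue tiles 58% and 78%. These shares hold for such counts and need not hold for the real libraries. Splits of the real libraries other than by treatment called a median of 82 CpGs in hippocampus and 159.5 in hypothalamus.

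Alternatives were a minimum of 20 reads, no filter on the pooled level, strands kept apart, tiles in place of CpGs, dispersion held at 1, edgeR's quasi-likelihood test, limma on mean tile levels, a block for the replicate number, leaving out CpGs whose level spans 50 points or more, leaving out each library in turn, and the fructose libraries for the tissue comparison. Added after seeing the data were CC methylation as a covariate or subtracted from non-CpG levels, a term for CC methylation over 1%, fits within replicates or libraries of like CC methylation, and a fit without the 3 shallow hypothalamus libraries. A minimum of 5 reads could not be run on tables that start at 10 reads. Other splits of the libraries into 4 and 4 were enumerated in full, 35 per comparison, with those balanced over CC methylation refitted with a batch term for hippocampus CpGs, and for the tissue by treatment term 20 relabellings were used, the real one included.

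Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.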

Results

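Reduced representation bisulfite sequencing measures cytosine methylation in the CpG-rich fragments that the enzyme MspI releases from the genome. It was applied to the hippocampus, a forebrain region of learning and memory, and to the hypothalamus, a region that governs feeding and energy balance, of male Sprague Dawley rats, an outbred stock. Each tissue had 4 libraries from control rats and 4 from rats that received fructose during a 6-week study, 16 libraries in all. The labels do not say whether the replicates of a group were separate animals. At 2,803 variable CpGs, 6 pairs of libraries across the tissues shared the class of level at 89.1% of CpGs or more. No other pair exceeded 51.9%, as described at the end. This argues against technical replicates of 1 rat for the matched libraries. The remaining libraries were hippocampus control replicate 4 and fructose replicate 4, and hypothalamus control replicate 1 and fructose replicate 4. A repeat of a matched rat would match that rat's library of the other tissue, and none of them did. This argues against repeats of a matched rat for them as well. Whether the unmatched hypothalamus libraries hold DNA of 1 rat each stays open, as described at the end. The libraries listed between 1,207,990 and 1,528,412 CpG cytosines, with a median of 25 to 46 reads each. Hypothalamus control replicate 1, hypothalamus fructose replicate 1 and hypothalamus fructose replicate 4 were the shallowest, with medians of 26, 29 and 25 reads. In total, 857,399 CpGs had at least 10 reads in all 16 libraries.

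Cytosines followed by another C are rarely methylated in mammals, so their apparent methylation tracks cytosines that bisulfite left unconverted. This CC level lay between 0.357% and 0.403% in replicates 1 and 2 of both hippocampus groups and between 1.81% and 1.91% in their replicates 3 and 4. In hypothalamus it ranged from 0.324% in control replicate 4 to 2.13% in fructose replicate 2. Apparent non-CpG methylation of mitochondrial DNA ranged from 0.245% in hypothalamus control replicate 4 to 2.83% in hypothalamus fructose replicate 2. Methylation before A, the form of non-CpG methylation that neurons carry, was above the CC level in every library, by 1.11 to 2.69 percentage points. In hippocampus the excess followed the CC level: 1.16 to 1.36 points in replicates 1 and 2, 2.51 to 2.69 in replicates 3 and 4. It did so less clearly in hypothalamus, at 1.36 points in control replicate 4 and 1.11 points in control replicate 1. In the CHH context, mitochondrial DNA of hippocampus control replicate 3 read 3.28% before A and 1.89% before C. The excess may therefore include unconverted cytosines and cannot be read as neuronal methylation alone.

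**Figure D1:**
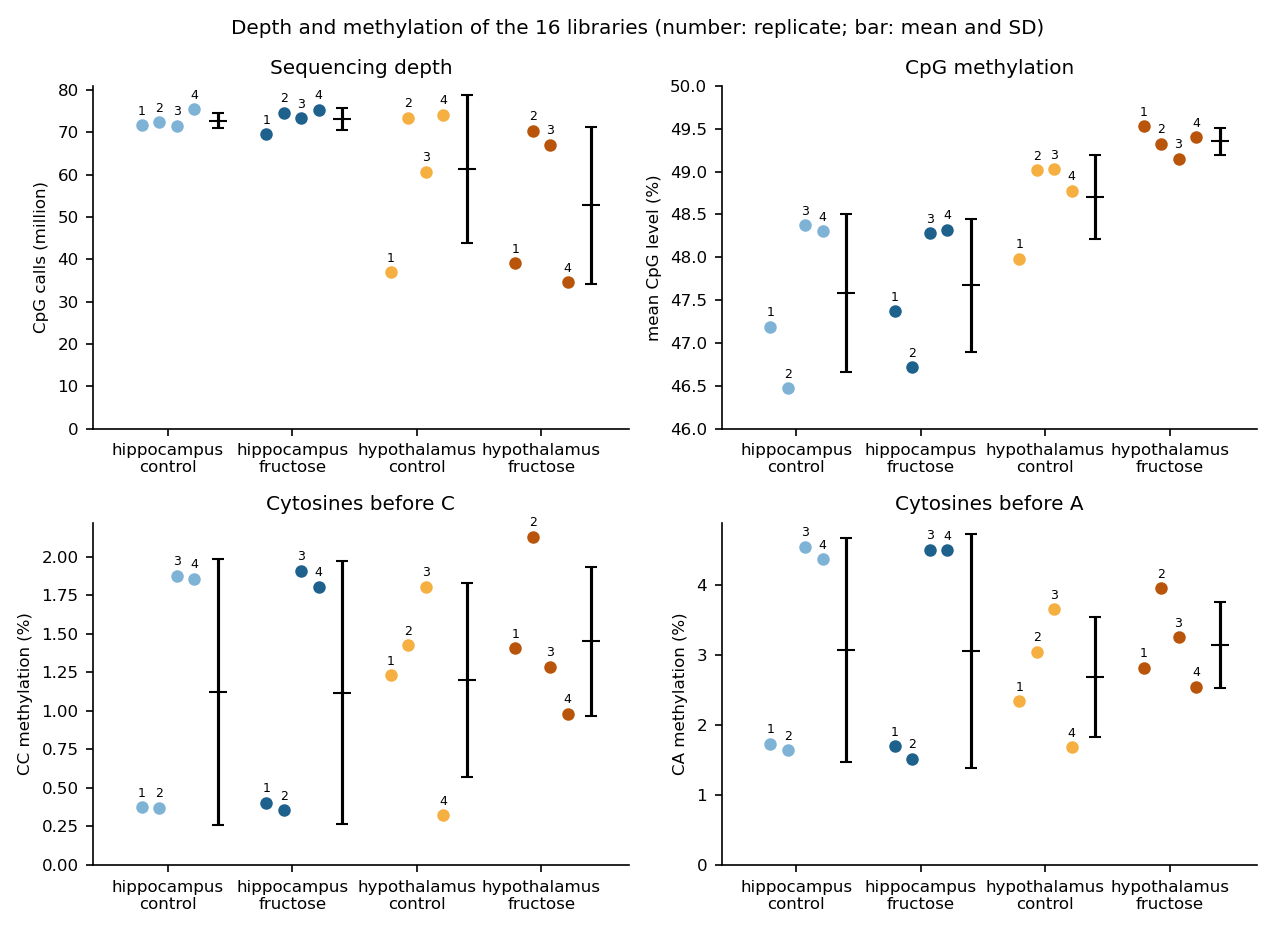
Depth (CpG calls), mean CpG level, CC methylation and CA methylation (each in percent) of the 16 libraries; each point is 1 library with its replicate number, and bars give the group mean and SD. The axis of the CpG panel does not start at 0. Hippocampus replicates 3 and 4 of both treatments had CC methylation of at least 1.81%, against at most 0.403% in replicates 1 and 2.

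The first comparison addressed whether fructose was accompanied by a change of DNA methylation in the hippocampus. Single CpGs differed strongly between the groups, while no difference in the genome-wide level was detected. A CpG on chromosome 2 at position 49310447 fell from 82.3% ± 3.50 (SD, n = 4) in control to 13% ± 17 (SD, n = 4) in fructose libraries, and one on chromosome 2 at 49178244 fell from 91.6% ± 0.942 to 27.5% ± 27.1. The CpG on chromosome 3 at 11463331 fell from 58.2% ± 19.5 to 0% in all 4 fructose libraries. In the other direction, the CpG on chromosome 3 at 70313399 rose from 11.4% ± 19.3 to 81.5% ± 22.4, and that on chromosome 4 at 196839878 rose from 1.22% ± 2.44 to 49.9% ± 17.5. Their adjusted p-values were 0.000812, 0.00225, 0.00204, 0.0335 and 0.00425 in the moderated quasi-binomial test with Benjamini-Hochberg adjustment, at 25 to 181 reads per library.

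In total, 68 of 592,234 tested hippocampus CpGs passed the threshold, of which 21 were higher and 47 lower with fructose. The absolute difference at these CpGs had a median of 34.6 percentage points, and 64 of them differed by 10 points or more. At 53 of the 68 the groups did not overlap. At 34 of the 68, or 50%, the level spanned 50 points or more over the 8 libraries, against 1.59% of all tested CpGs. Most of the called CpGs stood alone, with 20 lying within 1 kb of another called CpG. A run of 7 called CpGs on chromosome 14 between 46822747 and 46822848 fell by 6.96 to 11.4 points, and a run of 6 between 46861731 and 46861812 fell by 10.8 to 14.6 points. The run of 7 had 7762 to 8009 reads per library, close to the highest total of 8031 and far above the median of 54. Why its depth was so high was not examined, and its counts may not be those of an ordinary single site. Both runs were singled out after their values were seen.

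No 1 kb tile of 126,561 passed the threshold in hippocampus with the moderated quasi-binomial test, and none did with edgeR's quasi-likelihood test or with limma on mean levels. At an unadjusted p under 0.05 there were 3,286 tiles, or 2.60%. The smallest p belonged to the tile on chromosome 14 at 46861001 to 46862000 (14 CpGs), at 29.8% ± 1.69 (SD, n = 4) in control and 18.9% ± 2.29 in fructose libraries, adjusted p = 0.698. Next came the tiles on chromosome 1 at 25178001 (91.1% ± 1.41 against 74.7% ± 6.41) and on chromosome 15 at 41829001 (94.4% ± 1.65 against 84.5% ± 1.68), both with an adjusted p of 1.

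The mean CpG level of the hippocampus was 47.6% ± 0.919 (SD, n = 4) in control and 47.7% ± 0.775 in fructose libraries, a difference of 0.0886 points with p = 0.800 in a two-sided exact permutation test. Within the replicates of low CC methylation the difference was 0.212 points and within those of high CC methylation -0.0351 points, with 2 libraries a side and no test. Among CHG, CHH, CA, CT and CC methylation the largest difference was that of CA, at -0.0173 points, and exact permutation p ranged from 0.886 to 1.

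Leaving out any single library raised the count of called CpGs above 68. It was 180, 122, 109 and 146 without control replicates 1, 2, 3 and 4. Without fructose replicates 1, 2, 3 and 4 it was 115, 166, 75 and 111. With replicates 1 and 2 alone 759 CpGs passed, and with replicates 3 and 4 alone 1,211, each with 2 libraries a side. Of the 10 CpGs named by rule, those at 70313399 on chromosome 3, 23108576 on chromosome 15, and 246983994 and 196787615 on chromosome 4 lost their call without 1 or another of control replicates 1, 2 and 3 and fructose replicates 1, 3 and 4. The same 4 CpGs were not called by edgeR (adjusted p = 0.115, 0.219, 0.274 and 0.264) or at a minimum of 20 reads.

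**Figure D2:**
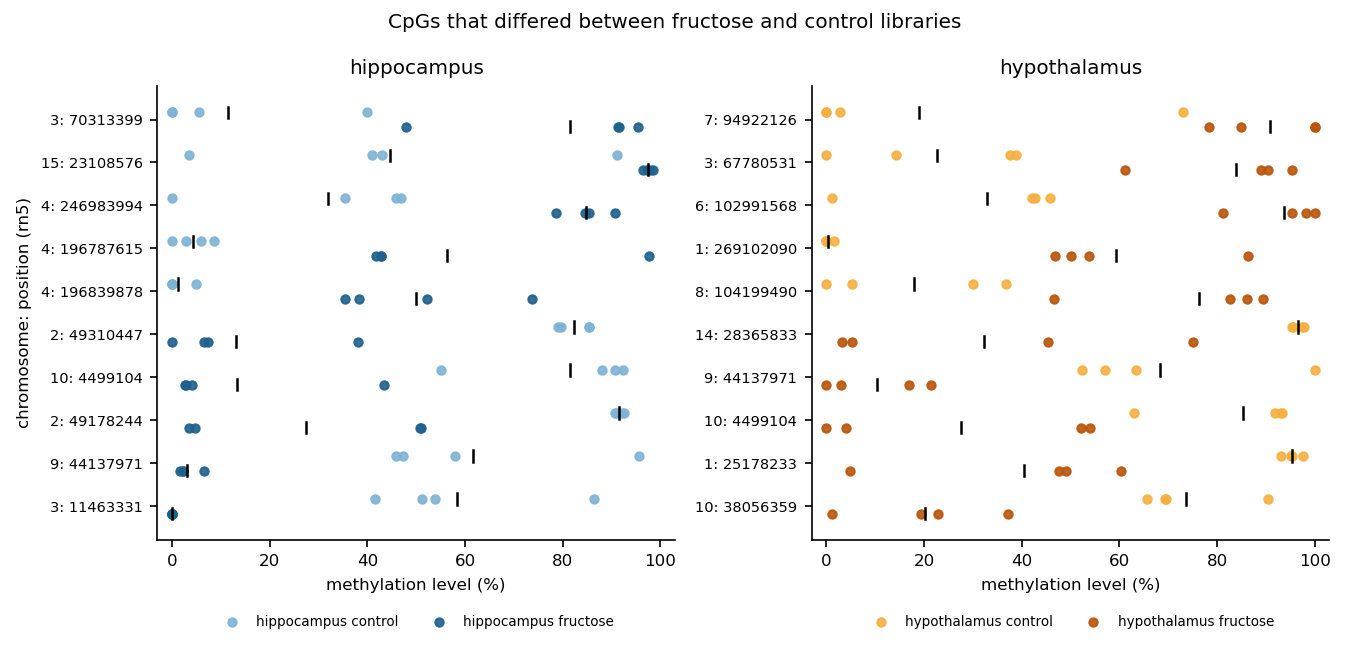
Methylation level (percent) in each library at the 10 CpGs per tissue with the largest rise and fall among called CpGs whose groups do not overlap, in hippocampus on the left and hypothalamus on the right; points are libraries and vertical bars group means. Many CpGs have libraries of 1 group far apart, such as the CpG on chromosome 3 at 70313399, where control libraries lie between 0% and 40%.

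In the hypothalamus the same question was asked of the fructose and control libraries of that tissue, and again single CpGs differed strongly. The CpG on chromosome 1 at 269102090 rose from 0.417% ± 0.833 (SD, n = 4) in control to 59.3% ± 18.3 (SD, n = 4) in fructose libraries, and that on chromosome 6 at 102991568 rose from 32.9% ± 21.2 to 93.7% ± 8.5. The largest rise was at 94922126 on chromosome 7, from 18.9% ± 36.0 to 90.8% ± 11. Falls were seen on chromosome 14 at 28365833, from 96.6% ± 1.27 to 32.2% ± 34.5, and on chromosome 1 at 25178233, from 95.3% ± 1.83 to 40.4% ± 24.4. Adjusted p-values of these CpGs were 4.25e-06, 0.000396, 0.0194, 0.000203 and 3.94e-05 in the moderated quasi-binomial test, at 23 to 274 reads per library.

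Of 468,823 tested hypothalamus CpGs, 131 passed the threshold, 79 higher and 52 lower with fructose. The median absolute difference was 35 percentage points, and 128 differed by 10 points or more. The groups did not overlap at 78 of the 131, and 80 of them, or 61.1%, spanned 50 points or more over the libraries, against 1.67% of tested CpGs. None of the 131 lay on the X chromosome, where 7,232 CpGs were tested. At the rate of 0.0279% over all tested CpGs only a few calls would fall there, so their absence says little.

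The 1 hypothalamus tile of 102,624 that passed the threshold lay on chromosome 14 at 43532001 to 43533000. Its level over 7 CpGs rose from 48.7% ± 2.43 (SD, n = 4) to 68.2% ± 3.03, adjusted p = 0.0272, at 306 to 980 reads per library. Neither edgeR (adjusted p = 0.443) nor limma (adjusted p = 0.155) called it, and the call was lost without control replicate 1, 2 or 3 or fructose replicate 1 or 2. With fructose replicate 3 left out 2 tiles passed, and with fructose replicate 4 left out 3. The tile on chromosome 14 at 28365001 to 28366000 did not pass, at 93.5% ± 1.58 against 60.8% ± 15 and an adjusted p of 0.160.

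The mean CpG level of the hypothalamus was 48.7% ± 0.493 (SD, n = 4) in control and 49.4% ± 0.159 in fructose libraries. All 4 fructose libraries, from 49.2% to 49.5%, lay above all 4 control libraries, from 48.0% to 49.0%. The difference of 0.650 points had p = 0.0286, the smallest that the two-sided exact permutation test can give here, and p = 0.171 after adjustment over 6 measures. It was 0.659 points among the 3 libraries a side with CC methylation over 1% and 0.623 points between the 2 libraries under 1%, whose CC methylation was itself unlike, at 0.324% in control and 0.981% in fructose. In the fructose group means, CC methylation was higher by 0.253 points and CHG methylation by 0.354 points (exact permutation p = 0.543 and 0.514), and apparent CpG methylation of mitochondrial DNA was 2.27% against 1.73%. CA methylation was 2.69% ± 0.855 in control and 3.15% ± 0.614 in fructose libraries, exact permutation p = 0.4.

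In the hypothalamus, too, leaving out any single library raised the number of called CpGs above 131, to at least 136. The number rose by over 1.5 times without control replicates 1, 2, 3 and 4, to 368, 318, 305 and 279. Without fructose replicate 2 it also rose by over 1.5 times, to 198. Without the 3 shallow libraries, which leaves control replicates 2, 3 and 4 and fructose replicates 2 and 3, 642 of 593,152 CpGs passed. Among them were 116 of the 131, which is no independent support, as these libraries also gave the 131. The CpGs at 94922126 on chromosome 7 and 67780531 on chromosome 3 lost their call without fructose replicate 3, the latter also without fructose replicate 1. With edgeR these CpGs (adjusted p = 0.115 and 0.147) and that at 104199490 on chromosome 8 (adjusted p = 0.107) were not called, and the CpG on chromosome 7 was also lost at a minimum of 20 reads.

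Between the tissues, 12 CpGs were called for fructose in both, 7 higher and 5 lower in each, and all 12 in the same direction. The lists were drawn from 428,174 CpGs tested in both tissues and are not independent, since most libraries of 1 tissue match a library of the other at variable CpGs. The CpG on chromosome 10 at 4499104 fell from 81.5% ± 17.7 to 13.2% ± 20.1 in hippocampus and from 85.3% ± 14.9 to 27.6% ± 29.5 in hypothalamus. On chromosome 9 at 44137971 the levels went from 61.7% ± 23.2 to 3.15% ± 2.28 and from 68.2% ± 21.7 to 10.3% ± 10.5, each a mean ± SD of 4 libraries. Over all called CpGs measured in the other tissue, the fructose minus control difference had the same sign there at 64 of 65 hippocampus CpGs and 120 of 131 hypothalamus CpGs.

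Whether the fructose difference itself depended on the tissue was tested in a fit of all 16 libraries, in which 0 of 464,125 CpGs and 0 of 102,541 tiles passed in the moderated quasi-binomial test. At an unadjusted p under 0.05 there were 29,527 CpGs and 6,060 tiles. The CpG with the smallest p, on chromosome 9 at 25940414, differed between fructose and control by -13.6 points in hippocampus and by 12.1 points in hypothalamus, adjusted p = 0.198. Without hippocampus control replicate 4 this CpG passed (adjusted p = 0.0365), and 1 CpG also passed without hippocampus control replicate 2. On simulated data of the same design, changes of 40 points in 1 tissue only were recovered at 44% of the changed CpGs, all of intermediate pooled level. For the mean CpG level, the fructose difference was larger in hypothalamus by 0.562 points, with a permutation p = 0.393, treatment labels being permuted within each tissue. Both the fit and this permutation treat the libraries of the 2 tissues as separate animals and make no use of the match between them.

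The last comparison set the hypothalamus of control rats against their hippocampus. Here 45,533 of 516,166 CpGs passed, or 8.82%, and 40,416 of them were higher in the hypothalamus while 5,117 were lower. The CpG on chromosome 1 at 93658813 stood at 37.1% ± 7.64 (SD, n = 4) in hippocampus and 93.1% ± 1.87 (SD, n = 4) in hypothalamus, and that on chromosome 12 at 52351453 at 40.9% ± 3.89 and 93.1% ± 3.59. Lower in hypothalamus were the CpGs on chromosome 16 at 61578673, with 87.5% ± 0.454 and 30.7% ± 10.8, and on chromosome 3 at 176621937, with 64.2% ± 8.30 and 9.20% ± 7.43. Their adjusted p-values were 3.50e-07 for each of the first pair, then 9.09e-06 and 0.000144, at 13 to 111 reads per library.

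Of 111,909 tiles, 10,216 passed, 8,971 higher and 1,245 lower in hypothalamus. The tile on chromosome 3 at 182769001 to 182770000 (6 CpGs) was at 33.8% ± 4.28 (SD, n = 4) in hippocampus and 76.6% ± 1.56 in hypothalamus. Tiles on chromosome 18 at 80063001 (42.7% ± 3.96 against 79.2% ± 2.35) and chromosome 16 at 70209001 (47.1% ± 4.07 against 81.1% ± 2.57) were also far higher in hypothalamus. On chromosome 10, the tiles at 102440001 and 102388001 were higher by 24.5 and 21.5 points. In the opposite direction, the tile on chromosome 3 at 176622001 to 176623000 (18 CpGs) was at 44.0% ± 2.49 in hippocampus and 12.9% ± 0.736 in hypothalamus, and that on chromosome 2 at 251302001 at 44.9% ± 4.97 and 14.1% ± 1.31. Neighbouring tiles on chromosome 3 at 48187001 and 48188001 differed by -14.3 and -16.0 points. The 16 tiles named by rule had adjusted p-values of at most 0.000413 and kept their call when any single library was left out.

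Called tiles lay close together at some places, counted as runs where at most 2 tiles lay between them. The 2 runs with the most called tiles, 5 each, were on chromosome 4 from 711001 to 718000, at 4.84% ± 1.01 in hippocampus and 13.2% ± 3.46 in hypothalamus, and on chromosome 7 from 130202001 to 130209000, at 52.3% ± 4.13 and 69.5% ± 1.40 (SD, n = 4 each). Among runs lower in hypothalamus, 3 tiles on chromosome 3 from 176621001 to 176624000 averaged 38.8% ± 2.57 and 11% ± 1.71, and 4 tiles on chromosome 5 from 133592001 to 133596000 averaged 39.2% ± 4.05 and 20.8% ± 3.56. These runs were picked by the number of called tiles, after the calls were known.

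Called CpGs were most frequent at intermediate mean levels, a class that the difference itself helps to fill, since the mean is taken over both tissues and levels near 0% or 100% leave little room to differ. Between 20% and 80% methylation 14.3% of 215,536 CpGs passed, against 5.13% below 20% and 4.80% above 80%. In tiles with 30 or more listed CpGs, which hold dense CpG clusters, 5.38% of CpGs passed, against 9.36% in tiles with 10 to 29 and 8.78% in tiles with fewer than 10. On the X chromosome 3.88% of 8,264 CpGs passed, against 8.90% on autosomes. CpG cytosines listed on the X chromosome had fewer reads on average in each control library, which makes a call less likely. How much of the lower share this explains was not tested. In each of these classes over 82% of the called CpGs were higher in hypothalamus.

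**Figure D3:**
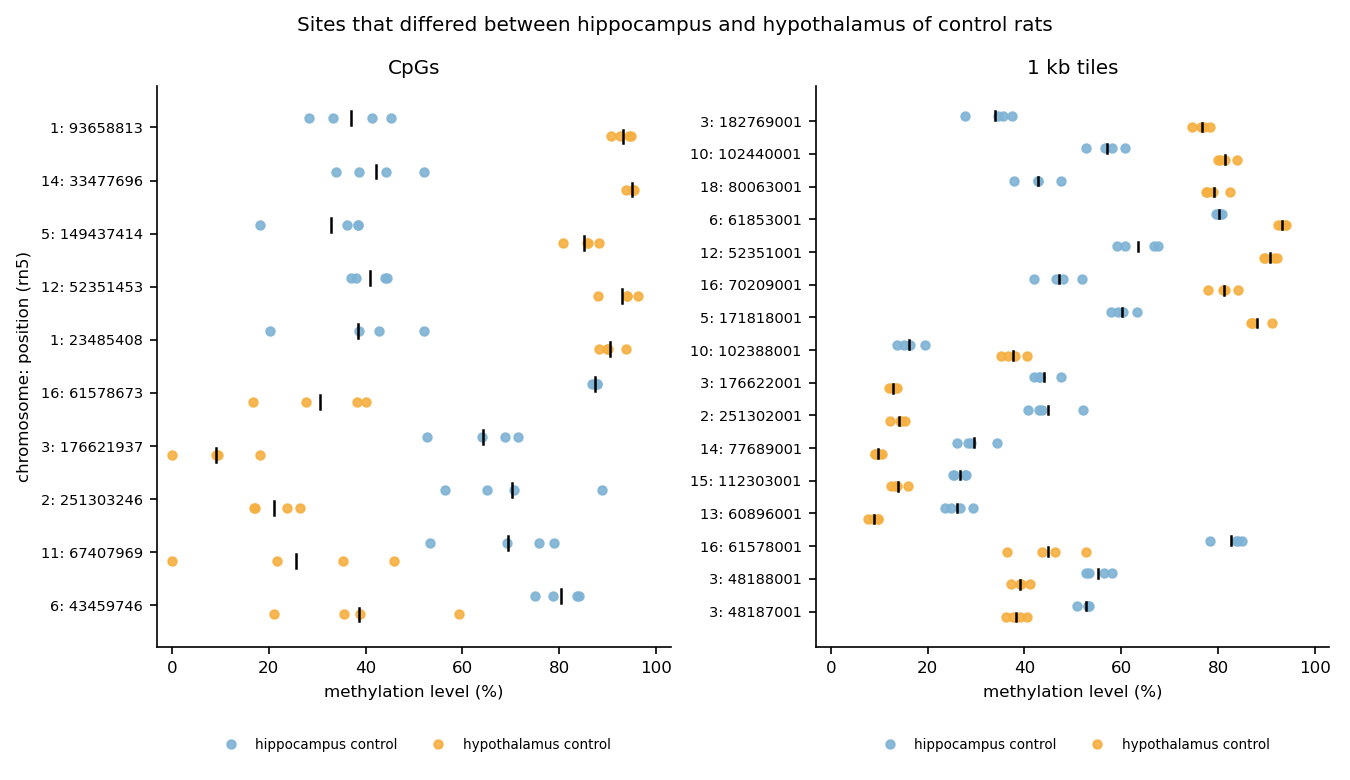
Methylation level (percent) in each control library of hippocampus and hypothalamus at the named CpGs (left) and 1 kb tiles (right); points are libraries, vertical bars group means, and tile labels give the tile's first position. At all of these sites the 4 libraries of 1 tissue lie apart from the 4 of the other, which for the CpGs was a condition of their choice.

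Averaged over all CpGs, the tissues differed less: 47.6% ± 0.919 in hippocampus against 48.7% ± 0.493 in hypothalamus (SD, n = 4 each), a difference of 1.12 points with two-sided exact permutation p = 0.0857. This test makes no use of the match between libraries of the tissues. In the matched pairs, examined after their values were seen and not tested, the hypothalamus library was higher by 1.83, 2.56 and 0.403 points in controls and by 2.17, 2.61 and 0.869 points in fructose rats, and the smallest difference of each group was in the pair whose hypothalamus library had the lower CC methylation. The difference was 1.95 points between libraries with CC methylation under 1%, with 2 hippocampus libraries against 1, and 0.34 points between those over 1%, with 2 against 3. CA methylation was 3.07% ± 1.60 and 2.69% ± 0.855, exact permutation p = 0.629. With libraries over 1% CC methylation alone, 14,031 CpGs passed, 83.2% of them higher in hypothalamus, and 4,614 tiles. The count of CpGs dropped to 30,120 without hippocampus control replicate 2 and 29,400 without hypothalamus control replicate 4, and that of tiles to 6,068, 6,591 and 6,038 without hypothalamus control replicates 2, 3 and 4.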

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

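Of the tests in this part, those of other treatment labels for the tissue by treatment term and those of splits balanced over CC methylation were chosen only after the result was seen.

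Fructose comparisons: as many CpGs as the 68 of hippocampus and the 131 of hypothalamus were called in 25 and in 27 of the 35 splits of the 8 libraries of each tissue, at most 208 and 433 in another split, and as many tiles as the 1 of hypothalamus in 11, at most 23, so for these counts grouping by chance cannot be excluded, although the share of hypothalamus CpGs at an unadjusted p under 0.05 was largest in the real split, by a small margin (7.07% against at most 7.05%). For hippocampus tiles the real count of 0 is reached by all 35 splits by construction and decides nothing, with at most 16,135 in another. The hippocampus split with 16,135 tiles sets replicates 1 and 2 against 3 and 4 and so follows CC methylation, a structure of the libraries unrelated to fructose; within those batches 759 and 1,211 CpGs and 0 and 3 tiles were called. The 18 splits balanced over the batches, as the real one is, are too few for a share under 0.05. As many CpGs as the real 68 were called in 12 of the 18, the real one included. The other balanced splits called a median of 82 and at most 149. With a term for the batch, 14 of the 18 called as many as the real 183, and the others had a median of 209 and at most 294. For incomplete conversion, the group difference in CC methylation was 5.94e-05 of the median difference of called CpGs in hippocampus and 0.00722 of it in hypothalamus. This test could not have come out otherwise, since CC methylation was at most 2.13% in any library and the medians were 34.6 and 35 points. In hippocampus each group also holds replicates of both batches. Unconverted cytosines at the CC rate are too few for differences of that size. Smaller differences, and conversion that fails at single sites, are not covered. Differences between individual rats, such as genotype, stay open and may account for many of these CpGs: at called CpGs the difference in the other tissue had a median ratio of 0.660 (95% bootstrap interval 0.602 to 0.715) for hippocampus and 0.800 (0.745 to 0.851) for hypothalamus. An effect of fructose common to both tissues would give such ratios too and also stays open, as no test here separates it from which rats fell in which group.

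Tissue comparison: no other split of the 8 control libraries called as many as the 45,533 CpGs or 10,216 tiles, with 562 and 5,032 at most. The real split was the 1 of 35 in each case, the smallest share that 35 splits can give. This argues against grouping by chance, with a far wider gap for CpGs than for tiles, but does not exclude it. The split with 5,032 tiles sets hippocampus replicates 1 and 2 and hypothalamus replicates 1 and 4 against the rest, which follows CC methylation. For incomplete conversion, the tissues' difference in CC methylation was 0.00434 of the median difference of called CpGs. This test could not have come out otherwise, since CC methylation of the control libraries was at most 1.88% and that median 17.7 points. Unconverted cytosines at the CC rate are too few for a difference of that size. Smaller differences, and conversion that fails at single sites, are not covered. Against unequal depth, 93.2% of the 971 CpGs called with every library thinned to 10 reads per CpG were higher in hypothalamus. Against different rats behind the 2 sets of libraries, 88.7%, 88.9% and 95.3% of called CpGs differed in the same direction in fructose pairs 1 to 3, which share most of their variable CpG levels. A pair higher in hypothalamus at every CpG would score about 88.8%, so pairs 1 and 2 do not speak for the CpGs lower in hypothalamus. At the CpGs called as higher, the median difference in the pairs was 13.2, 13.4 and 18.4 points. Their mean differences over all CpGs were 2.17, 2.61 and 0.869 points. A different mix of cell types, which the tissues may well have, was not tested because 0 of the called CpGs were tied to a gene, and it cannot be told apart from a difference within cell types.

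For the tissue by treatment term, the real count of 0 CpGs and 0 tiles is reached by all 20 relabellings of treatment by construction, with up to 194 CpGs and 7 tiles in another, so they decide nothing.

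A single library stood far from the other 3 of its group at 17 of the 118 groups examined at named CpGs and tiles, where chance gives about 1 in 20 for normal values; that rate is no yardstick here, since these sites were chosen for large differences and any level above 0% stands apart from 3 libraries at 0%. Among the hippocampus CpGs, on chromosome 3 at 70313399, 1 control library was at 40% against 0% to 5.56% in the rest and 1 fructose library at 48.0% against 91.2% to 95.3%. The fructose library at 97.7% on chromosome 4 at 196787615 stood above 41.7% to 42.9%, and the control library at 4.88% on chromosome 4 at 196839878 above 0% in the rest. On chromosome 10 at 4499104, 1 control library had 55.0% against 88.1% to 92.2% and 1 fructose library 43.4% against 2.75% to 4.03%. On chromosome 9 at 44137971, 1 fructose library had 6.56% against 1.69% to 2.17%.

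Among the hypothalamus CpGs, 1 control library had 73.0% against 0% to 2.78% on chromosome 7 at 94922126, 1 had 1.23% against 42.2% to 45.7% on chromosome 6 at 102991568, and 1 had 1.67% against 0% on chromosome 1 at 269102090. A fructose library on chromosome 8 at 104199490 was at 46.7% against 82.7% to 89.5%. Control libraries on chromosome 10 stood apart at 4499104, with 63.0% against 91.9% to 93.3%, and at 38056359, with 90.4% against 65.7% to 69.4%. In the tissue comparison, 1 hypothalamus library had 93.8% against 95.2% to 95.5% on chromosome 14 at 33477696, and 1 hippocampus library 18.2% against 36.2% to 38.5% on chromosome 5 at 149437414. The tile on chromosome 5 at 171818001 had 1 hypothalamus library at 91.0% against 86.8% to 87.2%, and that on chromosome 3 at 48187001 had 1 hippocampus library at 51.0% against 53.1% to 53.3%.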

How the results depend on the processing

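The number of called CpGs in both fructose comparisons moved with nearly every choice, while the tissue comparison kept its direction. For hippocampus CpGs, 68 as planned, the count was 35 at a minimum of 20 reads, 1608 with no filter on the pooled level, 118 with strands apart, 0 with tiles in place of CpGs, 5979 with dispersion held at 1, 22 with edgeR, 409 with a block for the replicate number and 144 without CpGs spanning 50 points. For hypothalamus CpGs, 131 as planned, the same choices gave 46, 2574, 202, 1, 7248, 37, 767 and 324. Among alternatives chosen after seeing the data, CC methylation as covariate gave 186 and 250, a term for CC methylation over 1% gave 183 in hippocampus, replicates 1 and 2 alone 759, replicates 3 and 4 alone 1211 (3 tiles), and hypothalamus without the 3 shallow libraries 642 (2 tiles). Hypothalamus tiles numbered 0 with limma, 0 with edgeR and 5 with the block. Tiles in place of CpGs kept the 5% to 95% filter of CpGs, so in the tissue comparison 12880 of 88046 were called, against 10216 of 111909 at 1% to 99%. Tissue CpGs numbered 90414 with dispersion held at 1 and, in an alternative chosen after seeing the data, 14031 with libraries over 1% CC methylation, where tiles numbered 4614. The tissue by treatment term gave 4831 CpGs and 13252 tiles with dispersion held at 1, and 1 CpG with the block. With dispersion held at 1 the spread between libraries is ignored by construction; for the other moves the cause was not tested.

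With each library left out in turn, counts ranged from 75 to 180 hippocampus CpGs, 0 to 1 hippocampus tiles, 136 to 368 hypothalamus CpGs, 0 to 3 hypothalamus tiles, 29400 to 47540 tissue CpGs, 6038 to 10204 tissue tiles, and 0 to 1 CpGs and 0 to 0 tiles for the tissue by treatment term. The mean CpG difference ranged from -0.282 to 0.407 points in hippocampus, 0.411 to 0.759 in hypothalamus and 0.748 to 1.38 between tissues. For CA methylation these ranges were -0.501 to 0.495, 0.128 to 0.786 and -0.866 to 0.105. Among the values of named sites over all alternatives, calls were lost at 20 of 170 for hippocampus CpGs, 7 of 148 for hypothalamus CpGs and 3 of 154 for tissue CpGs. For hypothalamus tiles 8 of 57 values were weaker and 6 stronger, and for the tissue by treatment term 6 of 93 CpG values and 5 of 93 tile values were stronger. No difference at a named site changed its sign, which says little. At the named CpGs and tiles of the comparisons between groups the groups do not overlap, so leaving out libraries cannot change the sign. A change of the test alone leaves the difference in level as it is. Replicate numbers do not pair the samples of the 3 comparisons: none of 4 same-numbered pairs correlated over 0.1 between treatments in either tissue or between tissues in controls, where the lowest was -0.24 (-0.367 in the top 1% of CpGs, -0.105 over all). Across tissues the fructose numbers 1 to 3 do pair the libraries, with correlations up to 0.511. The lowest of the 4, at 0.13 (0.244 and 0.0441), is that of replicate 4, whose libraries shared the class at only 50.6% of variable CpGs, and centring on group means gives such a remainder pair a positive value by construction. No fit by matched rat was made, since in the controls the match departs from the labelled numbers. A minimum of 5 reads, promoter windows and gene lists were not run. Depth limits which CpGs could be tested: 468823 in hypothalamus, and 593152 without its 3 shallow libraries.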

Other observations

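All tests in this part were chosen only after the result was seen.

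Called CpGs came in groups of 3 or more, with gaps of at most 1 kb, at 6 places. In hypothalamus, 3 CpGs on chromosome 14 between 43532502 and 43532529 stood at 49.3% ± 2.81 in control and 69.8% ± 1.56 in fructose libraries (SD, n = 4 each), while the same CpGs differed by -4.60 points in hippocampus. On chromosome 7 between 94922126 and 94922226, 3 CpGs were at 13.4% ± 20 and 76.1% ± 22.0, and differed by 59.8 points in hippocampus as well. On chromosome 19 between 5826886 and 5826966, 3 CpGs were at 25.9% ± 5.56 and 17.6% ± 5.03, with -8.36 points in hippocampus. In hippocampus, the 7 CpGs on chromosome 14 between 46822747 and 46822848 were at 36.8% ± 3.92 and 26.4% ± 4.28 with 7762 to 8009 reads, close to the ceiling of the tables, and the 6 CpGs between 46861731 and 46861812 at 31.2% ± 2.02 and 18.8% ± 2.26 with 271 to 387 reads. These 2 groups differed by -7.40 and -7.45 points in hypothalamus. On chromosome 1 between 13502915 and 13502979 the depth ranged from 10 to 5551 reads and the mean level differed by only -1.37 points. The levels there were 11.4% ± 1.73 in control and 10.1% ± 8.93 in fructose libraries. Adjusted p was nonetheless as low as 0.000275 in the moderated quasi-binomial test.

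CpGs that varied between the hippocampus libraries carried over to the hypothalamus library by library. At 2,803 CpGs whose level spanned 50 points or more in hippocampus, hypothalamus control replicates 2, 3 and 4 fell in the same class of level (below 25%, 25% to 75%, above 75%) as hippocampus control replicates 1, 2 and 3 at 95%, 92.3% and 93.7% of CpGs. Hypothalamus fructose replicates 1, 2 and 3 matched the hippocampus fructose replicates of the same number at 89.1%, 93.1% and 92.7%. No other pair of libraries reached more than 51.9%. This suggests that each matched pair comes from 1 rat, the lowest matched share being 89.1%, and the matched replicates of a group would then be different rats. In the controls the matched numbers differ by 1 between the tissues. A shared preparation batch is argued against, since matched libraries differed in CC methylation by 1.58 times the mean of all pairs across tissues.

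Hypothalamus control replicate 1 and fructose replicate 4 matched no hippocampus library. At 589 CpGs chosen in the matched hippocampus libraries and thinned to 20 reads, 14.8% and 13.2% of their levels lay between 10% and 30%, against 5.60% and 7.13% in the unmatched hippocampus libraries, control replicate 4 and fructose replicate 4. The highest share, 17.5%, was that of hypothalamus fructose replicate 1, which is also shallow but has a match. DNA of more than 1 rat in these libraries may explain this, and lower read depth may as well: the lower of these shares was 1.86 times the higher hippocampus one at equal reads, where 2 times or more would have spoken for mixed DNA against depth, so the test cannot tell these explanations apart. After that test had left the question open, and with the SDs already seen, the SD of levels at equal reads was also compared: it was at most 0.850 times that of either unmatched hippocampus library (95% bootstrap interval 0.823 to 0.896). This comparison was devised to fit what had been seen and decides nothing. In hypothalamus fructose replicate 1, CpGs near 0 in its matched library were higher by 13 points where other rats were methylated than where they were not, against at most 1.47 points in the other matched pairs, so DNA of a second rat is a candidate explanation there.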
